A study of Mus musculus with 3 samples.

How the data were processed

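RNA from male gonads of mouse embryos at stage E14.5 was measured on Agilent whole-genome oligonucleotide arrays in a single colour. Total RNA was amplified to cRNA carrying the dye Cy3, per the labels' protocols. Signals were read with Agilent Feature Extraction 9.5, per the submitters' processing notes. The table held 3 columns, a single column for each genotype. The labels named replicates 1 and 2 in the title of each column, so each column may be the mean of 2 arrays. How the arrays were combined is not given in the sources used here.

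The deposited values are ratios on a linear scale. The authors' normalization is not given in the sources used here, and the following description was inferred from the values. Most probes lay near 1, and no probe exceeded 1 by more than 0.1% in all 3 columns, so most probes appear to have been divided by their own middle value. A separate class of 7599 entries lay below 0.7 in all 3 columns. The negative control probe belonged to it, with deposited values of 0.352 in the control column, 0.354 in the Nanos2-/- Stra8+/- column and 0.454 in the column labelled Nanos2-/- Stra8-/-. For this class, and for others with a middle value far below 1 such as the Nanos2 probe, the divisor is unknown. The scaling between arrays remains unknown. The column medians over all probes were 0.941, 0.975 and 0.999 in the same order. A difference between columns is unaffected by a divisor per probe, but the deposited value of a probe says nothing about its brightness and cannot be set against that of another probe.

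Of 41267 entries, 93 control spots were left out and 41174 array probes were used. The platform's annotation gave 1 gene symbol for 32664 probes and several for 45, which were left unnamed together with 8465 probes it did not list. For 32524 probes the gene identifier was found in a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols and was used for names only. Each gene took the probe with the highest mean log2 value over the 3 columns, which gave 19532 genes. A gene passed the level filter if its value reached the column's median over all probes in at least 1 column, and 16629 genes did. This design had been written for a scale of signal levels. On values that are relative for most probes, neither the choice of probe nor the filter selects for brightness, and both were kept as written. The choice instead favours a probe with a high value in 1 column over flatter probes of the same gene. For Serbp1 it took a probe at 12.1 in the column labelled Nanos2-/- Stra8-/-, where its other probes lay at 1.17 and 1.14.

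The comparisons were log2 differences between columns. Nanos2 loss is the Nanos2-/- Stra8+/- column minus the Nanos2+/- Stra8+/- control column. Combined loss is the column labelled Nanos2-/- Stra8-/- minus the same control column. Stra8 loss on the Nanos2-/- background is the column labelled Nanos2-/- Stra8-/- minus the Nanos2-/- Stra8+/- column. With 1 column per group there was no test, no p-value and no error estimate. Genes were counted when the difference was at least 1 on the log2 scale, that is 2-fold. As a further count chosen after the data had been seen, genes with 2 or more passing probes were counted when every such probe differed by at least 2-fold in the same direction.

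The genes named in the text followed a rule fixed before the data were examined. It took Nanos2 and Stra8, then per comparison the 10 largest differences in each direction among genes with an established symbol whose passing probes all had the same sign, and up to 4 members with the largest absolute difference from each of 19 gene lists. Genes named outside the rule are said to have been chosen after their values were seen. The lists held 238 members, of which 218 were measured. They covered meiotic prophase, male germline methylation and piRNA, germ cell identity, pluripotency, Nodal and Activin signalling, retinoic acid, early oocytes, cell cycle, cell cycle inhibitors, p53 and apoptosis, Sertoli, Leydig, pre-granulosa, endothelial, macrophage, erythroid and mesonephric cells, immediate early and heat shock genes, and sex-linked genes. The median of each list was placed among 10000 random lists of the same size, matched in 20 bins of mean deposited value, which matches on no measure of brightness. This percentile describes these columns and is no test of the genotypes. The range of random lists is the middle 95% of their medians. For probes with a middle value near 1, the mean used for matching depends on the differences themselves. With Nanos2 loss the range ran from -0.31 to 0.66 for 10 early oocyte genes, but from -0.14 to 0.22 for 11 pluripotency genes. Percentiles of different lists therefore cannot be set against each other. A bootstrap range is the middle 95% of medians over 2000 resamplings of a list's own members. It shows the spread among the members and holds no variation between arrays or animals, so it is no confidence range for an effect of genotype.

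The counting steps were tested on simulated data with noise drawn from Stra8 loss on the Nanos2-/- background. For Nanos2 loss, run on 19532 genes, 84.0% of 50 genes changed 3-fold were counted, 98.0% of 50 changed 4-fold, 96.0% of 50 changed 8-fold and 90.0% of 50 changed 16-fold. Of 15516 unchanged genes, 5.60% passed the 2-fold size, against 8 of 6466 unchanged genes when every passing probe had to agree. The noise was drawn separately for each probe, so this low agreement was built in. Variation shared by the probes of a gene was not simulated, so the 8 genes give no rate of false calls for the counts by every probe. Of 200 unchanged lists, 6.00% fell outside the middle 95% of random lists. The 6 alternatives fixed before the data were examined were no level filter, a filter at the 75th percentile, centring of columns on their medians, quantile normalization, the mean over all probes of a gene, and raising values below a column's median to that median. A further alternative, centring each comparison on the median of the genes passing the filter, was chosen after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.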

Results

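Gene expression was compared in male gonads of mouse embryos at stage E14.5. At this stage of development the germ cells of the testis stop dividing, and those of the ovary enter meiosis. NANOS2 is an RNA-binding protein made by fetal male germ cells, and STRA8 is the retinoic acid-induced factor required for entry into meiosis. The study asked what the loss of Nanos2 does to the male germ cell programme with and without Stra8. The groups were gonads heterozygous for both genes, which served as the control, Nanos2-null gonads heterozygous for Stra8, and gonads labelled as null for both. Each group was represented by 1 column of array values, which the titles tie to replicates 1 and 2. No difference described here therefore has a replicate check, and the number of arrays limits the precision. RNA came from whole gonads, so germ cells and somatic cells were measured together. All values are deposited ratios, and 41174 probes for 19532 genes were used. Which values lay at background is not known, so a fold whose lower side lay there is only a lower bound.

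The targeted genes were examined before any other. Nanos2 had a deposited value of 87.2 in the control column, 0.364 in the Nanos2-/- Stra8+/- column and 0.397 in the column labelled Nanos2-/- Stra8-/-. It was thus lower in both, the direction that the labels call for. Whether the lower values lay above background is not known, so no fold is given. Stra8 had a deposited value of 0.108 in the control column, 1.13 in the Nanos2-/- Stra8+/- column and 1.34 in the column labelled Nanos2-/- Stra8-/-. By these values its single probe was 10.5-fold higher without Nanos2 and 12.4-fold higher in the column labelled as lacking Stra8 as well, sizes that depend on whether the low control value lay above background. The position of this probe relative to the deleted part of Stra8 is not given in the sources used here, so the probe cannot check that label, and directions drawn from this column rest on the label alone. The Y-linked genes Eif2s3y, Kdm5d and Uty had deposited values between 0.837 and 1.28 over the columns, and each stayed within 2-fold across them. With Xist, the X-inactivation RNA, this sex-linked list had a median of 0.21 with Nanos2 loss, at percentile 87.7 among random lists. The 4 probes of Xist disagreed, with log2 differences from 0.20 to 1.96 with Nanos2 loss and from -1.10 to 2.53 in combined loss.

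**Figure D1:**
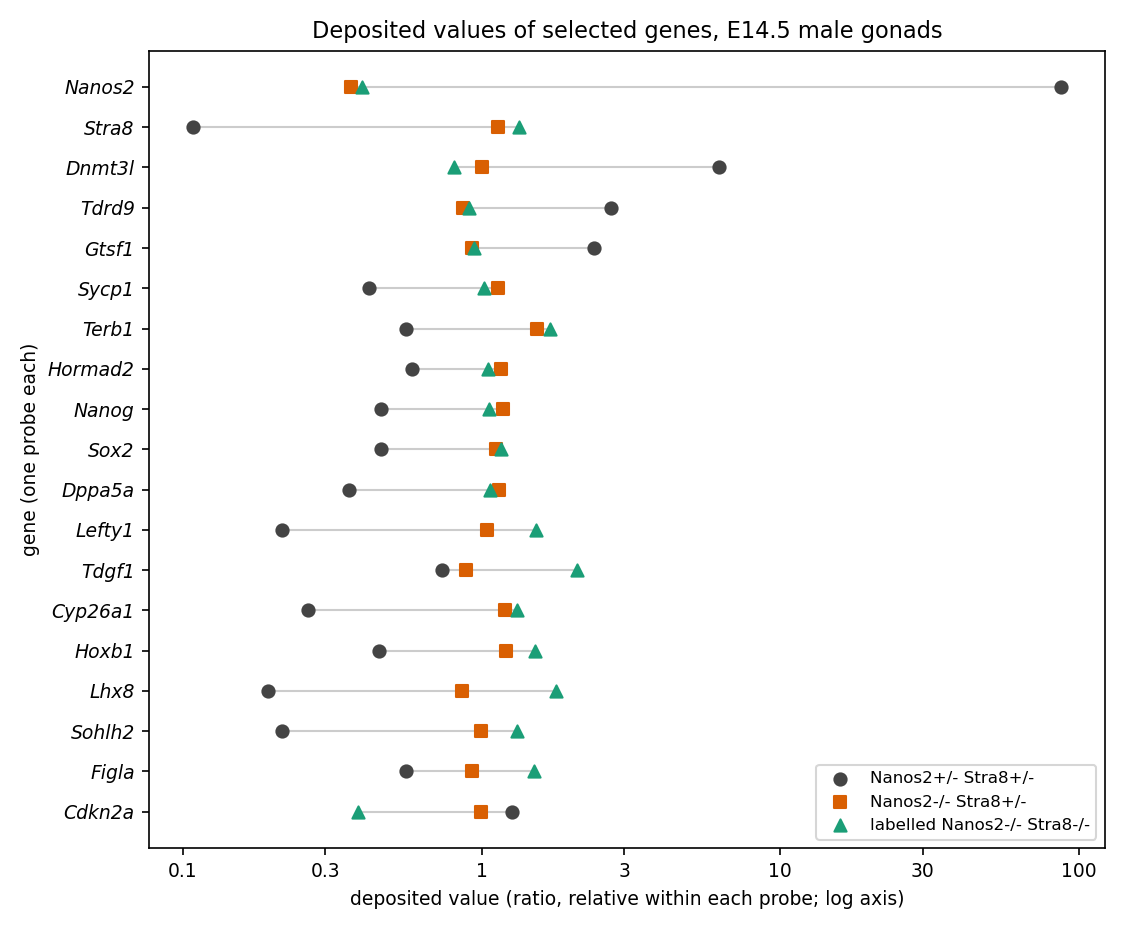
Deposited values of 19 genes, on a log axis, in the control column (circles), the Nanos2-/- Stra8+/- column (squares) and the column labelled Nanos2-/- Stra8-/- (triangles), with a single probe per gene and grey lines spanning the 3 values. Nanos2 lay at 87.2 in the control column and below 0.4 in the others, while Stra8 lay at 0.108 in the control column and above 1 in the others.

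Nanos2 loss was examined for the male germline programme, meiosis and genes of earlier or female germ cells. Genes of male germline DNA methylation and transposon silencing were lower in the Nanos2-/- Stra8+/- column. Dnmt3l, the cofactor of germline de novo DNA methylation, was 6.24-fold lower, and the piRNA pathway genes Tdrd9 and Gtsf1 were 3.13-fold and 2.56-fold lower. Genes of pluripotency and of female germ cells were among those higher than in the control column. Dppa5a was 3.18-fold, Nanog 2.56-fold and Sox2 2.42-fold higher. Sohlh2 and Lhx8, transcription factors of early oocytes, were 4.65-fold and 4.47-fold higher, although only 6 of 10 early oocyte genes lay above 0.

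The male germline methylation and piRNA list had 13 measured members passing the filter, of which 3 were at least 2-fold lower and 0 at least 2-fold higher. Only 1 of them had a difference above 0. The median of the list was -0.56 against 0.04 for all genes, at percentile 0.04 among random lists. The bootstrap range of this median, from -0.69 to -0.43, lay outside the range of random lists, from -0.25 to 0.19. Tdrd1, another piRNA pathway gene, was 1.61-fold lower. Chosen after its values were seen, Dnmt3a, a de novo DNA methyltransferase, had probes that disagreed, with log2 differences of -0.68, -0.55 and 0.11.

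The meiotic prophase list as a whole did not stand apart, although some of its members were higher. Its median over 25 genes was 0.01, at percentile 31.1, with 2 genes at least 2-fold higher and 1 at least 2-fold lower. Terb1, which attaches telomeres to the nuclear envelope in meiosis, was 2.75-fold higher, and Sycp1, the transverse filament of the synaptonemal complex, was 2.71-fold higher. Hormad2, a protein of meiotic chromosome axes, was 1.99-fold higher. Tex12, a central element protein of the synaptonemal complex, was 2.03-fold lower by both of its probes.

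The germ cell identity and pluripotency lists lay high among random lists with Nanos2 loss, with members on both sides of 0. The germ cell identity list had a median of 0.38 over 15 genes, at percentile 99.9, with 13 genes above 0 and 1 gene at least 2-fold higher. The bootstrap range of the median, from 0.10 to 0.70, overlaps the range of random lists, from -0.11 to 0.22. The gene at 2-fold was Taf7l, a germ cell form of a general transcription factor subunit, at 2.58-fold. Within the list Nanos3 was 1.77-fold and Dazl 1.68-fold higher, both regulators of germ cell RNA, while Dnd1 was 1.86-fold lower. The pluripotency list had a median of 0.37 over 11 genes, at percentile 99.9, with Dppa5a, Nanog and Sox2 as its 3 members at least 2-fold higher and Dppa4 at 1.84-fold lower. Only 7 of these 11 lay above 0, and the bootstrap range of the median, from -0.13 to 1.28, overlaps the range of random lists, from -0.14 to 0.22.

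Signalling genes gave smaller lists with few large differences, and the bootstrap ranges of their medians also overlap those of random lists. Of 7 Nodal and Activin genes, Lefty1, a secreted inhibitor of Nodal, was 4.83-fold higher and the median was 0.28, at percentile 98.4. Of 13 genes of retinoic acid metabolism and response, Cyp26a1, which degrades retinoic acid, was 4.55-fold higher and the target gene Hoxb1 was 2.66-fold higher, with a list median of 0.18 at percentile 97.54. Early oocyte genes went both ways. Of 10 members, Sohlh2, Lhx8 and Nlrp5, a maternal-effect gene at 2.97-fold, were at least 2-fold higher and Oog1 was 2.73-fold lower, with a median of 0.42 at percentile 83.8.

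Genes of the cell cycle and of most somatic cell types showed no large differences with Nanos2 loss. None of 17 cell cycle genes was at least 2-fold changed, with a median of 0.07 at percentile 71.3, nor was any of 9 cell cycle inhibitors, with a median of 0.20 at percentile 94.5. Of 13 p53 and apoptosis genes, Trp73 was 2.13-fold lower and the median was 0.11 at percentile 89.2. No Sertoli cell gene among 14 (median 0.02, percentile 34.1), no Leydig cell gene among 7 (median -0.04, percentile 19.4), no endothelial gene among 10 (median 0.03, percentile 51.0) and no macrophage gene among 9 (median 0.12, percentile 89.0) reached 2-fold. Pre-granulosa genes had a median of 0.11 over 9 genes, at percentile 76.0, and Gng13, a G protein subunit, was the only member to reach 2-fold, at 2.45-fold higher. None of 10 immediate early and heat shock genes reached 2-fold, with a median of 0.11 at percentile 85.7.

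Markers of red blood cells and of mesonephric epithelium also lay high among random lists with Nanos2 loss. The 7 erythroid genes had a median of 0.28, at percentile 99.7, with none at 2-fold and embryonic globin Hba-x at 1.42-fold, and the bootstrap range of the median, from 0.16 to 0.41, overlaps that of random lists, from -0.18 to 0.20. The 8 mesonephric genes had a median of 0.26, at percentile 99.6, and 3 were at least 2-fold higher. These were Ret, the GDNF receptor, at 4.14-fold, Lhx1, a homeobox factor, at 2.44-fold, and Cdh16, a renal epithelial cadherin, at 2.06-fold, while Pax8, a renal transcription factor, was 1.67-fold lower. The bootstrap range of the mesonephric median, from -0.40 to 1.29, overlaps the range of random lists, from -0.29 to 0.18.

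Over all genes, 414 were at least 2-fold higher and 637 at least 2-fold lower with Nanos2 loss, among 16629 passing the filter. Simulated unchanged columns, with noise drawn from Stra8 loss on the Nanos2-/- background, gave 285 and 276. That noise was centred on its median, alike in all columns, and came from a comparison without the control column. The observed differences had a standard deviation of 0.54, against 0.40 in the comparison that gave the noise. A noisier control column alone could therefore exceed the simulated counts. In the test of the counting steps for Nanos2 loss, 869 of 15516 unchanged genes passed the 2-fold size. That is a larger share than in the simulated columns, so the excess over 285 and 276 cannot be read as a number of changed genes. After Nanos2 the largest difference downward was that of Apoc2, an apolipoprotein that activates lipoprotein lipase, at 69.4-fold lower. Next were Clca1 at 30.5-fold, Trim61 at 27.6-fold, Vmn1r172 at 27.5-fold, Oas1d at 22.3-fold and Myl10, a myosin light chain, at 21.5-fold lower. Each had a single passing probe, and whether the lower values lay above background is not known. Trim61 lay at 6.64 in the control column and 0.241 in the Nanos2-/- Stra8+/- column, but at 0.946 in the column labelled Nanos2-/- Stra8-/-. By deposited values, the largest differences upward were those of Nrbf2, Stra8, Apobec4, Ptf1a, Fsd2 and the signalling gene Wnt8a, from 12.5-fold for Nrbf2 to 7.99-fold for Wnt8a. Nrbf2, an autophagy gene, had a second probe with a log2 difference of only 0.03. Of 7200 genes with 2 or more passing probes, 198 were at least 2-fold higher by any probe and 27 by every probe, and 234 were lower by any probe and 57 by every probe. With values below each column's median raised to that median, only 38 genes were higher and 344 lower, and 0 and 27 by every probe.

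**Figure D2:**
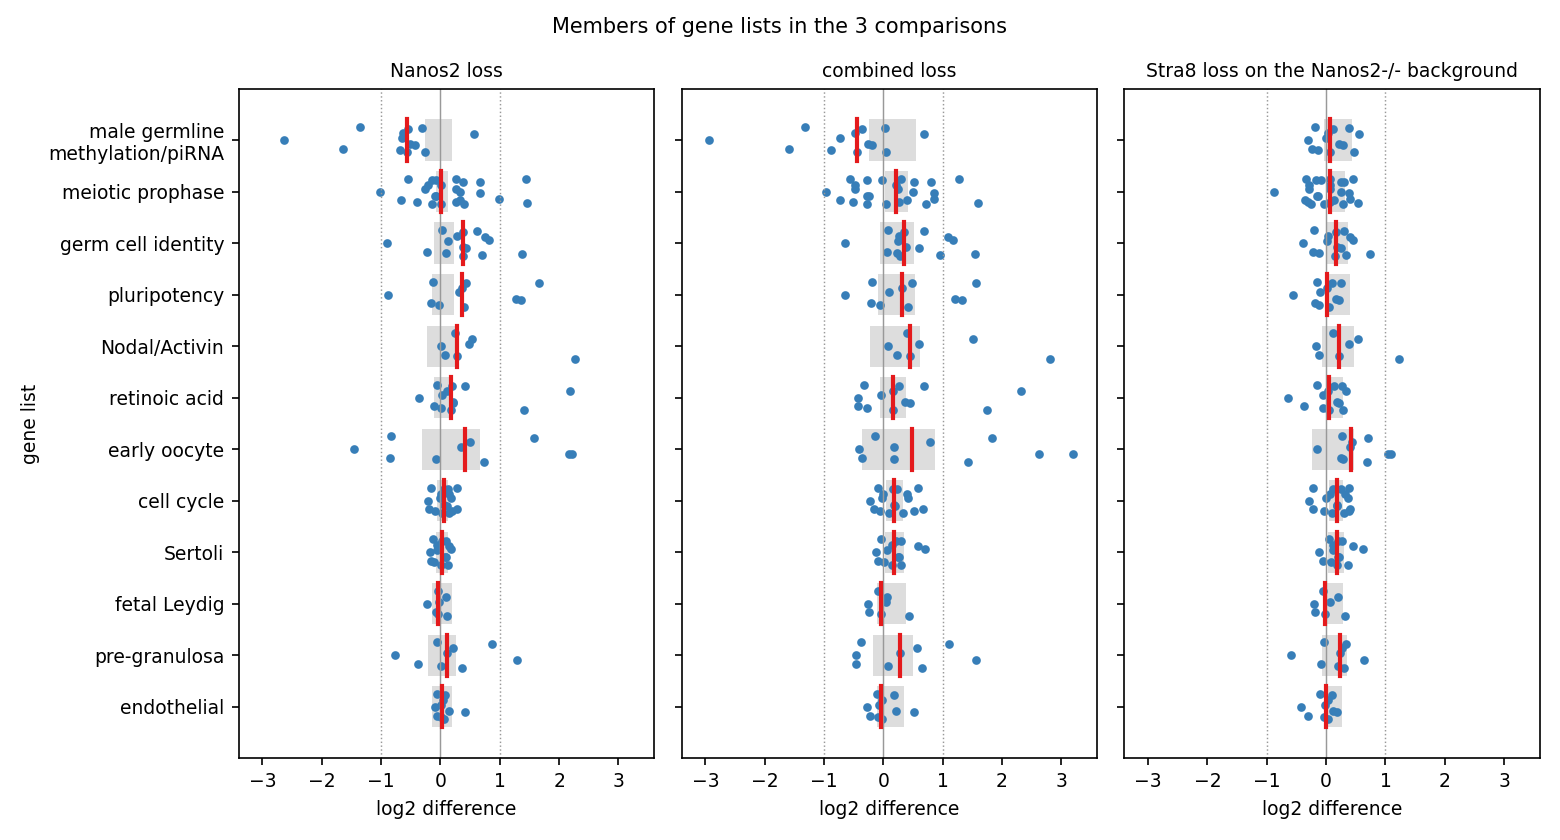
Log2 differences of members of 12 gene lists (points), list medians (red bars) and the middle 95% of medians of random lists (grey), for Nanos2 loss, combined loss, and Stra8 loss on the Nanos2-/- background, with dotted lines at 2-fold in either direction. The male germline methylation and piRNA list lies lower in the left and middle panels, with medians of -0.56 and -0.45, and near 0 in the right panel, with a median of 0.06.

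Combined loss was compared with the same control column to see which of these differences were present in the column labelled as lacking Stra8 as well. Male germline genes were again lower. Dnmt3l was 7.70-fold and Gtsf1 2.51-fold lower in the column labelled Nanos2-/- Stra8-/-, and Tdrd9 had a log2 difference of -1.59. Early oocyte and signalling genes were again among those higher, with Lhx8 at 9.20-fold, Lefty1 at 7.04-fold and Sohlh2 at 6.13-fold higher. Dppa5a was 2.96-fold, Sox2 2.51-fold and Nanog 2.30-fold higher.

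The male germline methylation and piRNA list had a median of -0.45 over 13 genes, at percentile 0.32, with the same 3 members at least 2-fold lower and 0 higher. Its bootstrap range, from -0.88 to -0.18, overlaps the range of random lists, from -0.24 to 0.55. The median of all genes was 0.19 in this comparison, so the list lay 0.64 below it. The meiotic prophase list had a median of 0.21 over 25 genes, at percentile 39.4, with 2 genes at least 2-fold higher and 0 lower. These were Terb1 at 3.03-fold and Sycp1 at 2.43-fold, the same members as with Nanos2 loss. Rec8, the meiotic cohesin subunit, was 1.80-fold higher and Tex15 was 1.95-fold lower.

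Other germ cell lists lay within the range of random lists in combined loss, although several members passed 2-fold. Of 15 germ cell identity genes, Taf7l at 2.91-fold, Alpl, an alkaline phosphatase of early germ cells, at 2.25-fold, and Prdm1, a determinant of primordial germ cells, at 2.14-fold were higher, with a list median of 0.35 at percentile 70.4. The pluripotency list had a median of 0.31 over 11 genes, at percentile 60.2. Of 7 Nodal and Activin genes, Lefty1 and Tdgf1, the Nodal co-receptor at 2.84-fold, were at least 2-fold higher, with a median of 0.46 at percentile 84.5. Cyp26a1, with a log2 difference of 2.32, and Hoxb1, at 3.34-fold higher, passed 2-fold among 13 retinoic acid genes, whose median of 0.16 lay at percentile 44.8. Of 10 early oocyte genes, Lhx8, Sohlh2, Nlrp5 at 3.57-fold and Figla, a factor for primordial follicles, at 2.68-fold were higher, with a median of 0.48 at percentile 73.8.

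Cell cycle and somatic lists again held few large differences. None of 17 cell cycle genes reached 2-fold, with a median of 0.18 at percentile 36.4. Among 9 cell cycle inhibitors, with a median of 0.21 at percentile 42.9, Cdkn2a, which encodes p16 and ARF, was 3.28-fold lower and Rb1, the retinoblastoma gene, was 2.0-fold higher. Among 13 p53 and apoptosis genes, with a median of 0.27 at percentile 77.5, Pmaip1, a mediator of apoptosis, was 2.48-fold higher and Trp73 2.26-fold lower, although a second probe of Trp73 had a log2 difference of 0.20. No Sertoli (median 0.18, percentile 42.2), Leydig (median -0.04, percentile 5.87), endothelial (median -0.05, percentile 7.35) or macrophage gene (median 0.15, percentile 48.3) reached 2-fold. Of 9 pre-granulosa genes, Gng13 was 2.97-fold and Rspo1, a WNT agonist of the ovary, 2.15-fold higher, with a median of 0.29 at percentile 73.7. The erythroid median was 0.28 at percentile 75.6. The mesonephric median was 0.35 at percentile 82.0, with Ret at 7.13-fold and Lhx1 at 2.17-fold higher. The immediate early and heat shock median was 0.33 at percentile 82.8, with no member at 2-fold.

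Over all genes, 819 were at least 2-fold higher and 628 lower in combined loss, so 56.6% of these were higher, while the simulated unchanged columns gave 280 and 277 genes. The simulation was centred, unlike these differences, and drew no noise from the control column, so it is no reference for the direction. Nor is it an upper bound for the number, since the test of the counting steps for Nanos2 loss passed a larger share of unchanged genes. Because the median of all genes was 0.19, centring on it gave 574 higher and 840 lower, or 40.6% higher, and the direction of the imbalance therefore depends on the scaling. The differences upward were largest for Ptf1a, a pancreatic and neural factor, with a log2 difference of 3.91, Nkx1-1 at 14.2-fold and Serbp1 at 13.5-fold. Serbp1, an mRNA-binding protein gene, rested on 1 of 3 probes, since the others had log2 differences of 0.45 and 0.44. The differences downward were largest, after Nanos2, for Apoc2 at 57.5-fold, Clca1 at 48.9-fold and Oas1d at 34.2-fold. These too had a single passing probe each, with lower values whose distance from background is not known. Every passing probe was at least 2-fold higher for 47 genes and lower for 53, against 424 and 607 for any probe. Among these genes with 2 or more passing probes the counts by any probe lean downward, so the imbalance also depends on the probe used. Averaging all probes of a gene gave 679 genes higher and 516 lower. Centring gave 24 higher by every probe, quantile normalization gave 34 lower, and raising values below each column's median to that median gave 3 and 26, with 162 genes higher and 329 lower by the single probe per gene.

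Nanos2 loss and combined loss shared much of their differences, but they also shared the control column. Of the 414 genes higher with Nanos2 loss, 281 were also at least 2-fold higher in combined loss (67.9%), and of the 637 lower genes 459 were also lower (72.1%). Simulated unchanged columns with a shared control gave 35.7% and 36.5%, and independent lists would share 20.4 and 24.1 genes. The correlation of log2 differences across the 16629 genes, which are not independent replicates, was 0.77 against 0.50 in the simulation. The covariance was 0.253 against 0.0799. Among genes whose every probe changed, 22 of 27 higher with Nanos2 loss were among the 47 of combined loss, and 40 of 57 lower were among the 53. With a single control column the controls could not be split, so part of the excess over either reference may come from that column.

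**Figure D3:**
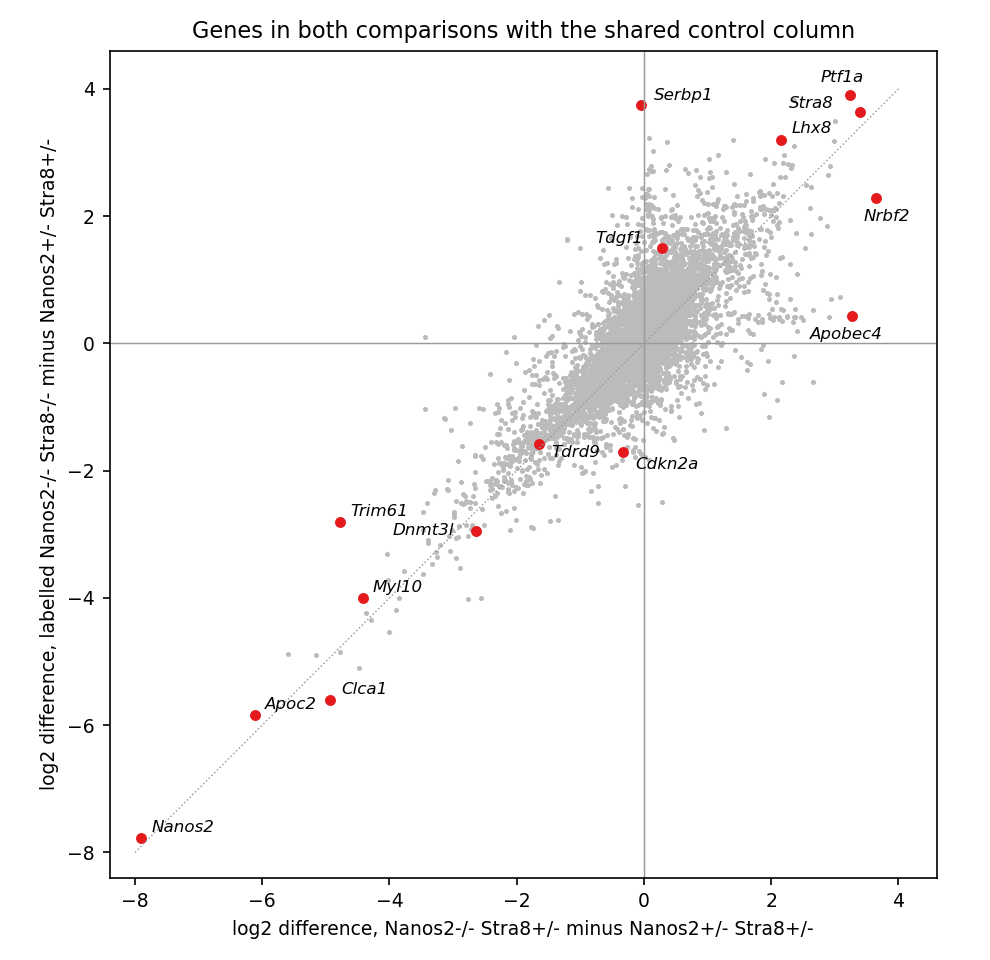
Log2 difference of each of 16629 genes with Nanos2 loss (horizontal axis) and in combined loss (vertical axis), both against the same control column, with selected genes in red and a dotted line of equality. Dnmt3l lies at -2.64 and -2.95, near the line, while Serbp1 lies at -0.04 and 3.75.

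Stra8 loss on the Nanos2-/- background compared the columns that differ in the Stra8 label alone, so its directions rest on a label that the Stra8 probe cannot check. The male germline genes Dnmt3l, Tdrd9 and Gtsf1 differed by less than 2-fold between them. Dnmt3l was 1.23-fold lower in the column labelled Nanos2-/- Stra8-/-, and Tdrd9 and Gtsf1, chosen after their values were seen, had log2 differences of 0.06 and 0.03. Lhx8 was 2.06-fold higher, and both of its probes passed 2-fold. Tdgf1 was 2.35-fold higher, and Cdkn2a was 2.60-fold lower. With values below each column's median raised to that median, the log2 difference of Cdkn2a was 0.00107.

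None of 25 meiotic prophase genes differed by at least 2-fold in the comparison for Stra8 loss on the Nanos2-/- background. Their median was 0.06 against 0.17 for all genes, at percentile 1.86 among random lists, and 8 of the 25 lay above the median of all genes, but its bootstrap range, from -0.17 to 0.24, overlaps that of random lists, from 0.07 to 0.32. Majin, a partner of Terb1 at meiotic telomeres, was 1.85-fold lower, while Sycp3, an axis protein, was 1.45-fold and Rec8 1.37-fold higher. The male germline methylation and piRNA list had a median of 0.06 at percentile 12.0, and none of its 13 genes reached 2-fold. Centred on the median of all genes, both lists had medians of -0.11, so the sign of these small medians depends on the scaling. Neither did any of 15 germ cell identity genes (median 0.17, percentile 34.2), 11 pluripotency genes (median 0.01, percentile 3.56) or 13 retinoic acid genes (median 0.05, percentile 10.5).

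Of the 10 early oocyte genes, Oog1 at 2.13-fold and Lhx8 were at least 2-fold higher, with a median of 0.41 at percentile 95.7. Tdgf1 was the only 1 of 7 Nodal and Activin genes to reach 2-fold, with a median of 0.22 at percentile 49.3. Cdkn2a was the only cell cycle inhibitor to do so, with a median of 0.20 at percentile 52.8. Cell cycle genes had a median of 0.18 at percentile 47.8, and p53 and apoptosis genes a median of 0.24 at percentile 82.9, with no member at 2-fold.

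Somatic lists were close to the median of all genes or somewhat below it. The medians were 0.19 for Sertoli genes (percentile 59.9), -0.02 for Leydig genes (percentile 4.87), 0.23 for pre-granulosa genes (percentile 76.8) and 0.00 for endothelial genes (percentile 5.82), with no member at 2-fold. Macrophage genes had a median of -0.02 at percentile 2.37 and erythroid genes of -0.06 at percentile 2.06, again with none at 2-fold. In the mesonephric list, with a median of 0.21 at percentile 56.5, Cdh16 had a log2 difference of -1.32. Fosb, an immediate early gene, was 2.52-fold lower in a list with a median of 0.20 at percentile 43.9. In the sex-linked list the probes of Xist disagreed, with log2 differences from -1.55 to 0.76.

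Over all genes, 384 were at least 2-fold higher and 204 lower with Stra8 loss on the Nanos2-/- background, so 65.3% were higher. Centring on the median of all genes gave 269 and 279, or 49.1% higher, and quantile normalization gave 390 and 331, or 54.1%. Averaging all probes of a gene gave 301 and 169. By any probe, among genes with 2 or more passing probes, 183 were higher and 446 lower, so the direction also depends on the probe used. The genes furthest upward were Serbp1 at 13.9-fold, by 1 of 3 probes, Mzt2 at 11.7-fold, Btla, an inhibitory receptor of lymphocytes, at 7.97-fold, and Mstn, the gene of myostatin, at 7.39-fold. Mzt2 was low in the Nanos2-/- Stra8+/- column alone, at 0.0922 against 1.005 in the control column. Whether that low value lay above background is not known. The genes furthest downward were Lmtk3 at 9.62-fold and Apobec4 at 7.15-fold. Both were high in the Nanos2-/- Stra8+/- column alone, at 3.53 and 2.24. Lmtk3 lay at 0.558 in the control column and 0.367 in the column labelled Nanos2-/- Stra8-/-, and Apobec4 at 0.233 and 0.313. Of 183 genes higher by any probe, 6 were higher by every probe, and of 446 lower by any probe, 3 were lower by every probe. Centring turned these into 3 higher and 6 lower, and raising values below each column's median gave 2 and 0, with 122 genes higher and 30 lower by the single probe per gene. Chosen after their values were seen, the 6 before centring were Prok2, Clic6, Elmod1, Mdfi, Cartpt and Lhx8, and the 3 were Zgrf1, Ddx23 and Ube2s. Of the 414 genes higher with Nanos2 loss, 79 (19.1%) were at least 2-fold lower in this comparison, and of the 637 lower genes 71 (11.1%) were at least 2-fold higher. Simulated unchanged columns, which share the Nanos2-/- Stra8+/- column in the same way, gave 35.9% and 36.3%. Their noise was centred, of equal size in all columns and drawn from this same comparison. A noisier control column alone could lower the observed shares, so the gap to the simulation cannot be read as an effect of genotype.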

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

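The 2-fold size and the filter used here were fixed before the data were examined, and the decision to look at probes without a gene name was taken afterwards. Probes that carry no gene symbol in the annotation used here entered none of the comparisons of genes. Of 5036 such probes passing the level filter, 82 were at least 2-fold higher in both Nanos2-/- columns than in the control column, and 139 were at least 2-fold lower in both. These are 1.63% and 2.76% of such probes, against 1.69% and 2.76% of the 16629 genes with a name, and 0.61% each in simulated unchanged columns that share a control. The named genes and the simulation used 1 chosen probe per gene, so neither is a like reference for single unnamed probes. The counts of 82 and 139 both rest on the same control column. No other result was singled out, since each group held a single column.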

How the results depend on the processing

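The alternative that centred each comparison on its median, the counts by every probe and the gene families were chosen after the data had been seen. The alternatives were run for the genes named by the fixed rule, not for those chosen after seeing their values. Apart from Cdkn2a, none of the former with a difference of at least 2-fold reversed its direction under an alternative that kept it, and the male germline list stayed below 0 with Nanos2 loss and in combined loss under all of them. The counts stayed within 1.5 times of the reported ones under no filter, the stricter filter, column centring and, for counts of genes, probe averaging. Raising values below a column's median to that median had the strongest effect. It gave 38 genes higher and 344 lower with Nanos2 loss, 162 and 329 in combined loss, and 122 and 30 with Stra8 loss on the Nanos2-/- background. Counts by every probe became 0 higher and 27 lower, 3 and 26, and 2 and 0, in the same order. The male germline median became -0.39 instead of -0.56 with Nanos2 loss. Cdkn2a, lower with Stra8 loss, became 0.00107. Because most values lie near 1 and each column's median is also near 1, this setting removes most of any difference below the middle by its construction. Quantile normalization gave 331 genes lower with Stra8 loss instead of 204, and 34 instead of 53 lower by every probe in combined loss. The cause was not tested. Centring each comparison gave 24 genes higher by every probe in combined loss instead of 47, and 3 higher and 6 lower with Stra8 loss instead of 6 and 3. This follows from the shift of all differences by 0.19 and 0.17. Among named genes, 104 differences moved by more than the spread between probes of a gene when low values were raised, 51 under quantile normalization and 30 under probe averaging. Leaving out replicates was not possible with 1 column per group. No paired analysis was possible because each group has a single column. Signal over background was not analysed here, so how many differences lie near background is open.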

Other observations

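The gene families and single genes in this part were chosen after their values had been seen, as were the tests of probe agreement and of a background offset. Genes with symbols of homeobox families, most of which encode transcription factors of patterning, were examined in this way. Of 87 passing genes, which include 4 antisense transcripts, 11 were at least 2-fold higher and 4 lower with Nanos2 loss, with a median of 0.13 at percentile 99.2 among random lists. In combined loss 15 were higher and 2 lower, with a median of 0.38 at percentile 99.9, and with Stra8 loss on the Nanos2-/- background 6 were higher and 0 lower, with a median of 0.23 at percentile 95.3. Without the members that had drawn attention or stood in other lists, 78 genes remained, of which 5 were higher and 4 lower with Nanos2 loss and 7 and 2 in combined loss. Their medians lay at percentiles 88.6 with Nanos2 loss, 98.2 in combined loss and 97.2 with Stra8 loss. The combined-loss median of 0.327 lay just above the range of random lists, which ended at 0.320. Leaving out the antisense transcripts too gave percentiles of 83.0 with Nanos2 loss, 94.1 in combined loss and 97.1 with Stra8 loss, all within the range of random lists. Examples are Otx2, a regulator of head development, with log2 differences of 2.89 with Nanos2 loss and 2.65 in combined loss, and Nkx2-2, a neural and pancreatic factor, with 1.26 and 1.93.

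Further genes were changed by each of their probes. Spic, an ETS-family factor, was higher by at least 1.71 on the log2 scale with Nanos2 loss and by at least 1.86 in combined loss, and Wnt3 by at least 1.27 and 1.16. The interferon-inducible GTPases Tgtp1 and Irgm1 were higher by at least 1.66 and 1.34 with Nanos2 loss, whereas Oas3 and Ifi27l2a, also interferon-inducible, had differences of -2.03 and -2.01 or lower. The zinc-finger factor Zic1 was at -2.89 or lower with Nanos2 loss and at -2.29 or lower in combined loss. The 381 odorant, vomeronasal and trace amine receptor genes passing the filter were at least 2-fold higher in 15.5% of cases with Nanos2 loss, 34.4% in combined loss and 12.9% with Stra8 loss, against 2.18%, 4.23% and 2.06% of other genes. They were at least 2-fold lower in 2.62%, 3.15% and 4.46% of cases, against 3.86%, 3.79% and 1.15% of other genes. A gene low in most columns passes the filter only if its value reaches the median of another column, which builds in a large difference. How many receptor genes passed in this way was not counted, so these shares cannot be read as a change in receptors. Probes below 0.7 in all 3 columns also had median differences of 0.37 in combined loss and 0.30 with Stra8 loss.

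Many genes passed the 2-fold size in a single comparison, and the agreement between probes limits how such a gene can be read. Of the genes with several passing probes and any probe at 2-fold, 19.4% were changed by every probe with Nanos2 loss, the highest share over the comparisons, against 9.70% in combined loss and 1.43% with Stra8 loss. This is in line with signal near background on single probes as a candidate explanation for many of the differences. A background offset in the column labelled Nanos2-/- Stra8-/- may add to them. The difference of this column from the Nanos2-/- Stra8+/- column was 0.18 higher in the class of probes below 0.7 than in probes passing the filter. The negative control probe, a member of that class, read 0.454 against 0.354, the direction that such an offset would give. It is a single entry, and the brightness of the other probes is not known, so the size of any offset stays open. Probes for different transcripts of a gene would also disagree, which was not tested.

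Of 55 passing genes of the ciliary axoneme, 16 were at least 2-fold lower with Nanos2 loss and 12 in combined loss, among them Drc1, Cfap44 and Cfap206. A single scaling factor per column would leave them at the median of all genes, but the 49 genes that had not drawn attention lay -0.27 from it. Signal near background on single probes would scatter them like random lists, and their median of -0.23 lay at percentile 0.0, but this explanation stays open because the random lists match on no measure of brightness. Cells with motile cilia in the control gonads remain open, because the 5 measured markers went both ways, with a median of -0.13 and Foxj1, their master regulator, at 0.82. A feature of the single control column, which combined loss shares with a median of -0.18, cannot be told apart from an effect of Nanos2.

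Several genes of striated muscle were also lower in both Nanos2-/- columns, including the myosin heavy chain gene Myh2 and the giant sarcomere genes Ttn and Neb. Their log2 differences were -2.71, -1.72 and -1.81 with Nanos2 loss. Over all passing probes they ran from -2.04 to -2.71 for Myh2, -1.17 to -1.72 for Ttn and -1.02 to -2.22 for Neb. In combined loss every passing probe was at least 2-fold lower for Myh2, from -1.97 to -2.86, but not for Ttn and Neb. For muscle tissue carried into the control gonads, the bound set was a median of -1 or lower in abundant fetal muscle genes. The 12 of these that passed had a median of -0.022, with a bootstrap range from -0.64 to 0.20. A smaller carry-over need not reach that bound and is not excluded. Among these fetal muscle genes Acta1 was at 0.22, Actc1 at 0.07 and Myh3 at -0.02, but Tnnc2 at -2.05, Ckm at -0.95 and Mylpf at -0.83. Against signal near background on single probes, the median of 42 genes of sarcomere and myosin families that had not drawn attention lay at percentile 1.49 among random lists, and that of the 34 left without non-muscle and smooth muscle myosins at percentile 0.24, but the bootstrap range of the latter, from -0.41 to 0.01, overlaps that of random lists, so this stays open. No explanation other than these was tested.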
